A study of Chlorocebus sabaeus with 18 samples.

How the data were processed

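Total RNA of COS-7 cells was extracted with a Qiagen kit and DNase and made into ribosomal-RNA-depleted TruSeq libraries, per the labels' protocols. Reads were trimmed with cutadapt 1.14 and aligned with STAR 2.5.2 to the human assembly GRCh38.p10, per the submitters' processing notes, although the cells are of the green monkey. Those notes also list DESeq2, without a version or a role. Reads of sequences that differ between the species can be lost in such an alignment.

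The authors deposited a table of normalised values per exon bin for 15 libraries, which is a signal scaled by 1 factor per library. They also deposited 6 DEXSeq tables with the raw counts per bin of the libraries compared, p-values and adjusted p-values, and log2 fold changes of relative bin use, per the file headers. A read that spans several bins is counted in each, so a sum over bins exceeds the number of reads. The 5 EventPointer tables deposited by the authors hold a p-value, a z score and a change in percent spliced in, as a fraction, for each of 6311 events, per the file headers. The direction of the change is not stated. It was read as the first-named group minus the second, which had the same sign as the bin counts for 22 of 22 cassette exons in CGG vs CTL, 25 of 25 in TRA_OE vs CTL and 2 of 2 in CGG_siTRA vs siTRA. The log2 changes deposited by the authors as first group over second were turned into treated over control where needed.

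The 3 CGG_TRA samples have no count or normalised column, so their gene and bin tests were not run. Count columns were assigned to groups by the tables' names and library numbers. The numbers in the columns could not be tied to the replicate numbers of the sample titles, so libraries are lettered here. For 2 CGG_siTRA samples the title names a round without saying of what, and no column carries it.

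Counts of the same library in different DEXSeq tables differed in 0 cells. Dividing the normalised values by 1 factor per library gave whole reads, within 0.1 of a read, for 100.0% of values, and these equalled the deposited counts wherever both were listed. A further 1623 cells above 0 that no table of the library listed were filled from the recovered reads. The 431444 bins of the DEXSeq tables were summed to 19997 genes or groups of overlapping genes, of which 1905 were groups. Bins outside these tables, mostly of genes with a single bin, held 1.56% to 2.10% of a library's reads. Of 23133 single Ensembl IDs, 0 were paired with a name in the reference table of the monkey assembly mChlSab1.0.hap1, and the files pair none. The gene lists fixed in advance could therefore not be tested, and at most 2 IDs that rose and 2 that fell are printed.

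Gene tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, Benjamini-Hochberg adjusted p under 0.05) on genes with a normalised count of 10 or more in at least 3 libraries. All 15 libraries entered a fit of 5 group means, so that they share the estimate of the spread. The plan was limma on log2 values with a pseudocount of 1 if only normalised values were deposited, and edgeR if counts were. The comparison of TRA_OE with siTRA was added after the data were examined, because the authors deposited a table for it.

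Bin use was tested with edgeR's diffSpliceDGE on the counts, over genes with at least 2 bins of 10 or more in 3 libraries. The plan was limma's diffSplice on log2 values with a pseudocount of 1. That test failed on simulated data for CGG vs CTL: of its 1973 calls among 265486 bins, 1813 were in genes without a changed bin, against 3 of 143 for diffSpliceDGE. In that simulation diffSpliceDGE recovered 53% of bins changed 1.5-fold and 87% of those changed 2-fold, and diffSplice 20% and 81%. limma's diffSplice is therefore kept as an alternative. The test was changed after the data were examined. The simulated counts were drawn bin by bin from the count model that diffSpliceDGE assumes. That favours its low number of false calls, so the simulation does not show that its calls in the real libraries are sound. Fits that left out a library or regrouped libraries kept the trended dispersion of the full fit for bins.

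The gene test was checked on simulated counts for 14969 genes with 200 changed, at 1.5-fold or 2-fold. edgeR recovered 71% and 78% of these for CGG vs CTL, 58% and 74% for CGG_siTRA vs CGG, and 68% and 80% for CGG_siTRA vs siTRA. Its false calls were 4 of 153, 4 of 136 and 10 of 158. These counts too were drawn from the model that edgeR assumes.

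Comparisons, tests, the rule for naming genes and most alternatives were fixed before the data were examined. Genes named are those with the largest rise and fall per comparison, at most 2 of each, in place of the 10 of each first planned, among single genes with an adjusted p under 0.05, a mean of 50 or more in the higher group and no overlap between the 3 libraries of each group. For the interaction the mean over all libraries had to reach 50. Bins and events named are at most 5 per table with the smallest p among those with a log2 change of 1 or more and a mean of 50 or more, or a change of 0.2 or more for events. Events were counted at an EventPointer p under 0.001 and a change of 0.1 or more.

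Alternatives were limma 3.58.1 with pseudocounts of 0.5, 1 and 5 or quantile normalisation, DESeq2 1.42.0, no filter, other scaling, only the groups compared, other bin minimums, and leaving out each library. Chosen after the data were examined were the authors' scaling factors, the highest bin per gene, all genes with recovered reads, leaving out overlapping gene groups, and leaving out siTRA library b everywhere. Bin totals per library, the measure of depth, were 121142115 to 203957869. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.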

Results

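RNA was sequenced from COS-7 cells, a kidney line of the African green monkey. The 18 samples formed 6 groups of 3: untreated controls (CTL), cells transfected with 60 CGG repeats in the FMR1 leader (CGG), cells overexpressing the splicing factor TRA2A (TRA_OE), cells with TRA2A knocked down (siTRA), and cells with the repeat plus overexpression (CGG_TRA) or plus knockdown (CGG_siTRA). None of these groups is named as an empty-vector or control-siRNA group. A difference from CTL can therefore hold an effect of transfection itself as well as one of the named treatment. The same holds for CGG_siTRA vs CGG, where the siRNA was added, and for CGG_siTRA vs siTRA, where the repeat was. Expanded CGG repeats underlie the tremor and ataxia disorder FXTAS named in the series title, which concerns the recruitment of TRA2A by RNA. Counts were deposited for 15 libraries of 5 groups, with totals over exon bins from 121142115 to 203957869, and CGG_TRA was represented only by the authors' splicing tables. Libraries are lettered a, b and c within each group here. Genes carry human Ensembl IDs, the files do not pair these IDs with names, and genes other than TRA2A are given by their GRCh38 position. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples.

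The manipulated gene moved as the labels say in each library. The gene ENSG00000164548.10 (chromosome 7, 23504780 to 23532041, minus strand) was the only 1 at least 2-fold higher in TRA_OE than in CTL and at least 2-fold lower in both knockdown comparisons, and it is taken here as TRA2A. Because it was picked by this behaviour, it is a weak check of the labels. Its normalised count was 17100 ± 166 (SD, n = 3) in CTL and 16250 ± 701 (SD, n = 3) in CGG. In TRA_OE it rose to 204600 ± 17300 (SD, n = 3). Knockdown left 3914 ± 917 (SD, n = 3) in siTRA and 4274 ± 220 (SD, n = 3) in CGG_siTRA. The log2 changes were 3.57 (SE 0.11, adjusted p = 8.46e-13) in TRA_OE vs CTL, -2.07 (SE 0.11, adjusted p = 1.61e-10) in siTRA vs CTL and -1.83 (SE 0.11, adjusted p = 5.36e-09) in CGG_siTRA vs CGG, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The repeat alone gave -0.05 (SE 0.10, adjusted p = 0.767, edgeR with Benjamini-Hochberg adjustment).

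**Figure D1:**
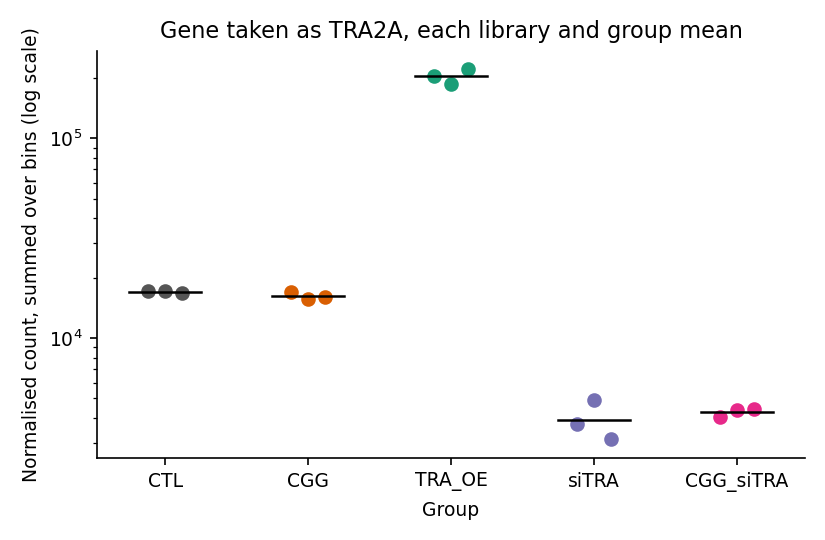
Normalised count of the gene taken as TRA2A, summed over its exon bins, on a log axis for each of the 15 libraries, with a line at each group mean. TRA_OE libraries lie near 204600, CTL and CGG near 17100 and 16250, and both knockdown groups near 3914 and 4274.

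Only part of the bins of the TRA2A locus rose in TRA_OE. Counts per bin do not tell transcripts of the cell's own gene from those of an introduced copy, so the rise cannot be assigned to either. Bins from 23506138 to 23506206 and from 23512894 to 23513024 rose to 10.56 and 16.04 times the CTL mean in TRA_OE. By contrast, the outermost 3' bin above the minimum, 23504784 to 23505248, stayed at 1.05 times CTL, and the bin from 23522132 to 23522353, between the raised exons and the 5' end, stayed at 0.87 times. The bin from 23531789 to 23531980, near the 5' end, reached 6.07 times. Knockdown lowered the 3' bin to 0.28 times CTL in siTRA and 0.24 times in CGG_siTRA. It left 0.47 and 0.53 times CTL of the bin from 23522132 to 23522353.

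**Figure D2:**
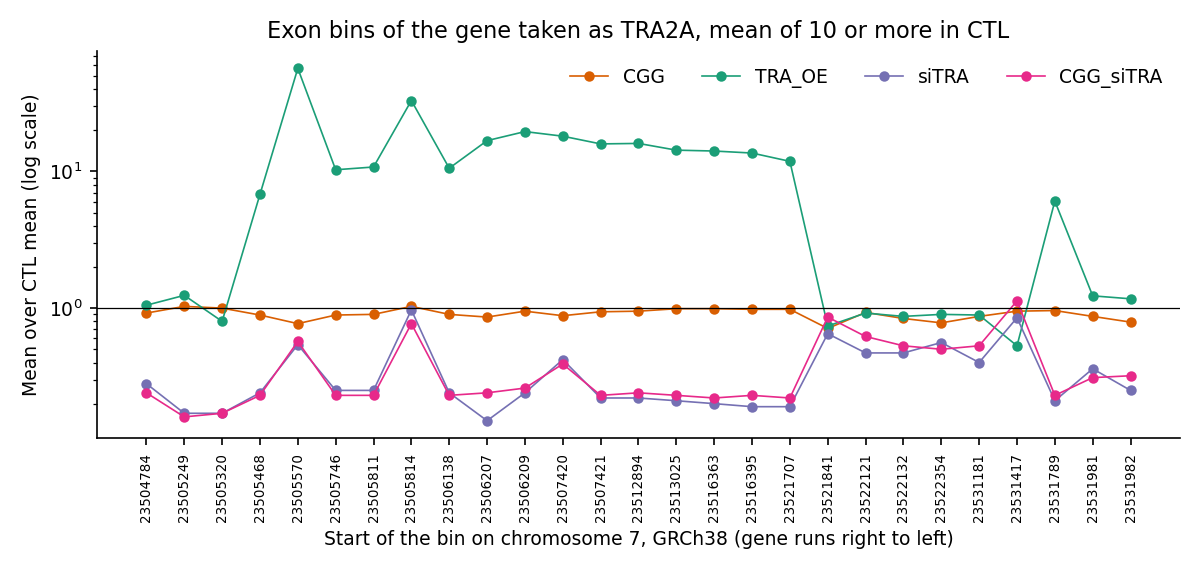
Mean normalised count of each exon bin of the gene taken as TRA2A over the CTL mean, on a log axis, for bins with a CTL mean of 10 or more, ordered along chromosome 7. In TRA_OE the bins from 23505468 to 23521840 lie between 6.80 and 56.81 times CTL, while the 3' end and the bins from 23521841 to 23531680 stay at 0.53 to 1.24 times.

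Genes were both higher and lower in cells transfected with the expanded repeat than in CTL. At chromosome 7, 134527592 to 134541408, a gene (ENSG00000198074.9) rose from 685 ± 51.3 in CTL to 12690 ± 274 in CGG (SD, n = 3). Its log2 change was 4.23 (SE 0.16, adjusted p = 4.89e-12, edgeR with Benjamini-Hochberg adjustment). At chromosome 19, 48755559 to 48758330, a gene went from 6.17 ± 2.05 to 89.35 ± 6.95 (SD, n = 3). At chromosome 1, 11857464 to 11858931, a gene (ENSG00000120937.8) fell from 1512 ± 114 to 204.7 ± 17.5 (SD, n = 3), a log2 change of -2.86 (SE 0.19, adjusted p = 7.21e-09, edgeR with Benjamini-Hochberg adjustment). A further gene at chromosome 6, 93240020 to 93419547, fell from 55.2 ± 10.7 to 5.86 ± 3.00 (SD, n = 3). In all, 3613 of 14969 genes changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), with 1776 higher and 1837 lower. The authors' scaling factors gave 1492 higher and 2079 lower, and limma with a pseudocount of 1 gave 1494 and 2058. The median absolute log2 change was 0.39, and 174 rose and 184 fell at least 2-fold. Fitting only the libraries of these groups called 6295 genes.

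In TRA_OE far more genes were strongly lower than strongly higher when set against CTL. Of the genes that changed at least 2-fold in TRA_OE vs CTL, 77 were higher and 362 lower. At chromosome 2, 96497646 to 96505357, a gene rose from 3.16 ± 2.86 to 50.3 ± 10.3 (SD, n = 3). At chromosome 12, 190077 to 210043, a gene fell from 61.5 ± 18.3 to 4.12 ± 3.92 (SD, n = 3), and the gene at chromosome 17, 6684713 to 6713567, fell from 160 ± 52.8 to 20.7 ± 11.2 (SD, n = 3). Their log2 changes were -3.82 (SE 0.81, adjusted p = 0.00189) and -2.98 (SE 0.51, adjusted p = 0.000283) by edgeR with Benjamini-Hochberg adjustment. Neither fall was particular to TRA_OE. The chromosome 17 gene lay at 20.25 ± 3.44 in siTRA and 50.37 ± 32.3 in CGG (SD, n = 3). The chromosome 12 gene lay at 12.42 ± 4.19 in CGG and 21.09 ± 18.3 in siTRA (SD, n = 3). At every size of change together the directions were even, with 2174 genes higher and 2144 lower among 4318 called.

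More genes differed from CTL in siTRA than in CGG or TRA_OE when all libraries shared the spread. When each pair of groups was fitted alone, fewer did. The chromosome 7 gene at 134527592 to 134541408 rose here too, from 685 ± 51.3 to 9263 ± 2330 (SD, n = 3; log2 change 3.83, SE 0.16, adjusted p = 1.49e-11, edgeR with Benjamini-Hochberg adjustment). So did the gene at chromosome 2, 96497646 to 96505357, which reached 51.5 ± 14.1 (SD, n = 3). At chromosome 3, 111592900 to 111595443, a gene fell from 73.7 ± 8.11 to 8.065 ± 3.21 (SD, n = 3), and the gene at chromosome 12, 71439770 to 71586306, from 94.5 ± 35.0 to 9.58 ± 8.32 (SD, n = 3). The chromosome 12 gene was also low in CGG, at 22.56 ± 10.4, and in TRA_OE, at 18.94 ± 8.06 (SD, n = 3). The edgeR test with Benjamini-Hochberg adjustment called 5667 genes, 2691 higher and 2976 lower. With the authors' scaling factors the split was 1963 higher and 3658 lower. Fitted alone, siTRA vs CTL gave 4766 genes, against 5625 for TRA_OE vs CTL and 6295 for CGG vs CTL. Library b of siTRA correlated least with the other libraries (mean r across genes 0.982, against 0.988 to 0.991 for the rest), and without it 5662 genes were called.

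**Figure D3:**
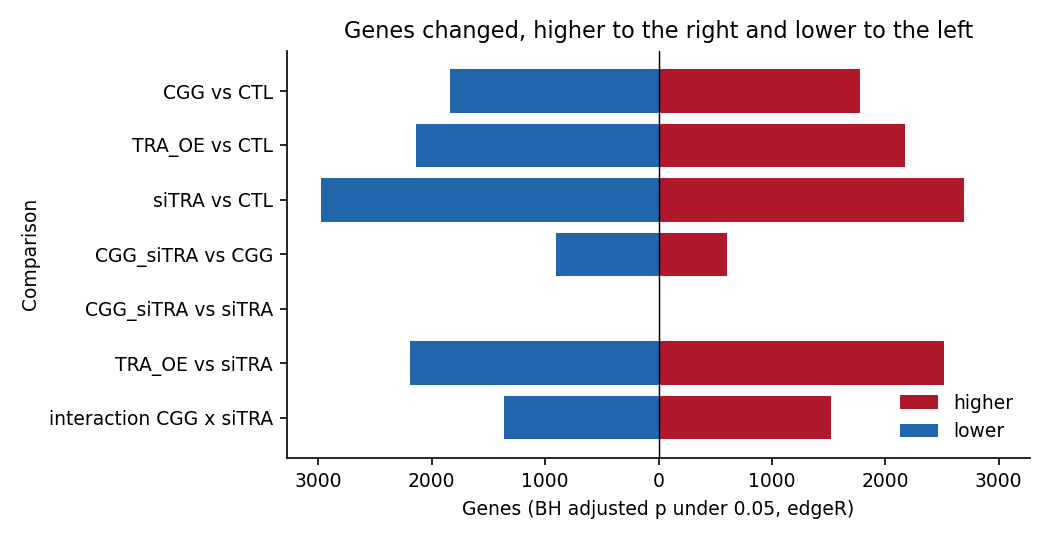
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 (edgeR) per comparison, higher to the right of 0 and lower to the left. siTRA vs CTL has 5667 genes, CGG_siTRA vs siTRA 2.

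The treated groups shared many changes against CTL. At chromosome 1, 11857464 to 11858931, the gene lay at 1512 ± 114 in CTL, 231.8 ± 40.0 in TRA_OE, 301.7 ± 85.9 in siTRA and 324 ± 90.8 in CGG_siTRA (SD, n = 3). The chromosome 7 gene at 134527592 to 134541408 was at 5576 ± 560 in TRA_OE and 8967 ± 575 in CGG_siTRA (SD, n = 3). Against CTL, 835 genes were higher and 995 lower in CGG, TRA_OE and siTRA alike. CGG and TRA_OE shared 1123 rises and 1228 falls, where independent lists of these sizes would share 258 and 263. CGG and siTRA shared 1270 and 1386 (independent lists 319 and 365), and TRA_OE and siTRA 1147 and 1214 (391 and 426). In 20 simulations of unchanged groups against the same controls, at most 1 gene was called in both lists. With no gene changed, few could be called at all. This therefore gives no value for how far shared controls raise the overlap of long lists. The fold changes correlated across genes at r = 0.65, 0.71 and 0.53 for these pairs (Spearman's rho 0.67, 0.66 and 0.50), where the simulations gave 0.49, and genes are not independent replicates. Their covariances were 0.161, 0.189 and 0.152, against simulated values of 0.0406, 0.0409 and 0.0410. The 3 CTL libraries cannot be split with at least 2 on each side, so part of the excess of the overlaps over independent lists may come from the shared controls.

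Knocking down TRA2A on top of the repeat moved fewer genes. At chromosome 15, 41230839 to 41281890, a gene (ENSG00000187446.11) fell from 32300 ± 706 in CGG to 7544 ± 954 in CGG_siTRA (SD, n = 3; log2 change -2.0, SE 0.08, adjusted p = 5.5e-11, edgeR with Benjamini-Hochberg adjustment). It fell likewise from 28280 ± 545 in CTL to 8110 ± 1030 in siTRA, and lay at 29490 ± 1090 in TRA_OE (SD, n = 3). At chromosome 10, 62811996 to 62816366, a gene rose from 30.9 ± 14.3 in CGG to 96.3 ± 11.4 in CGG_siTRA (SD, n = 3; adjusted p = 0.0021, edgeR with Benjamini-Hochberg adjustment). A gene at chromosome 17, 28703197 to 28711854, rose from 30.8 ± 16.7 to 69.6 ± 8.23 (SD, n = 3; adjusted p = 0.0271, edgeR with Benjamini-Hochberg adjustment), and its adjusted p lay between 0.0711 and 0.149 without CGG library a or c or without CGG_siTRA library a or b. In all 1507 genes changed, 603 higher and 904 lower, and 17 rose and 30 fell at least 2-fold. The authors' scaling factors gave 293 higher and 2037 lower, with the median log2 change of all genes at -0.093 and not 0.007, and 941 genes were called without CGG_siTRA library b.

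Effects of the knockdown treatment recurred in part between libraries that share no control. Without a control-siRNA group, an effect of lower TRA2A cannot be told apart from another effect of the siRNA. Of the genes changed in siTRA vs CTL, 905 changed the same way in CGG_siTRA vs CGG, where independent lists would give 288, and 135 changed the opposite way, where they would give 282. At chromosome 15, 41230839 to 41281890, the gene was among those lower in both. Across all tested genes the fold changes correlated at r = 0.176 (jackknife SE over libraries 0.031, Spearman's rho 0.205). Among genes with a mean of 100 or more, r was 0.327. In TRA_OE vs CTL, 406 genes moved opposite to CGG_siTRA vs CGG (independent lists 218) and 194 the same way (independent lists 217), and r across genes was -0.066 (jackknife SE 0.026, Spearman's rho -0.116). Of all tested genes other than TRA2A, 54.6% had opposite signs. Genes lower in both knockdowns showed no excess of that size, with 90 higher in TRA_OE (independent lists 85.5) and 116 lower (84.4). For those higher in both, 44 were lower (45.1) and 66 higher (45.7). These last counts share CTL libraries, so a tie to the TRA2A level is not decided. In all, 3 correlations of fold changes between comparisons without a shared library were computed, described by their jackknife errors and not by p-values.

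Between CGG_siTRA and siTRA, set apart by the transfected repeat, 2 genes changed. At chromosome 9, 128149441 to 128153455, a gene rose from 227 ± 28.4 in siTRA to 595 ± 26.0 in CGG_siTRA (SD, n = 3), a log2 change of 1.45 (SE 0.17, adjusted p = 0.00064, edgeR with Benjamini-Hochberg adjustment). At chromosome 12, 57516588 to 57520517, a gene rose from 4223 ± 245 to 6735 ± 598 (SD, n = 3), a log2 change of 0.73 (SE 0.08, adjusted p = 0.00064, edgeR with Benjamini-Hochberg adjustment). In CGG these genes lay at 568 ± 15.7 and 6761 ± 22.4, and in CTL at 88.0 ± 27.1 and 1696 ± 83.7 (SD, n = 3). In TRA_OE, which lacks the repeat, they lay at 635.3 ± 98.9 and 6259 ± 566 (SD, n = 3), so the rise over CTL was not particular to the repeat. Among the treated groups with counts, siTRA was lowest at both. Without an empty-vector group, the repeat cannot be told apart from its transfection. Of the 14969 genes, 2819 had an unadjusted p under 0.05. DESeq2 called 287 higher and 253 lower. limma called 2 higher and 3 lower with each pseudocount, and 2 higher and 0 lower with quantile normalisation. The fit of these groups alone called 1 gene, and in it the chromosome 12 gene had an adjusted p of 0.0629 (edgeR with Benjamini-Hochberg adjustment). The count was 682 without CGG_siTRA library a and 5 without library c. Fold changes for the repeat with and without the knockdown correlated at r = -0.041 across genes (jackknife SE 0.059, Spearman's rho -0.061).

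**Figure D4:**
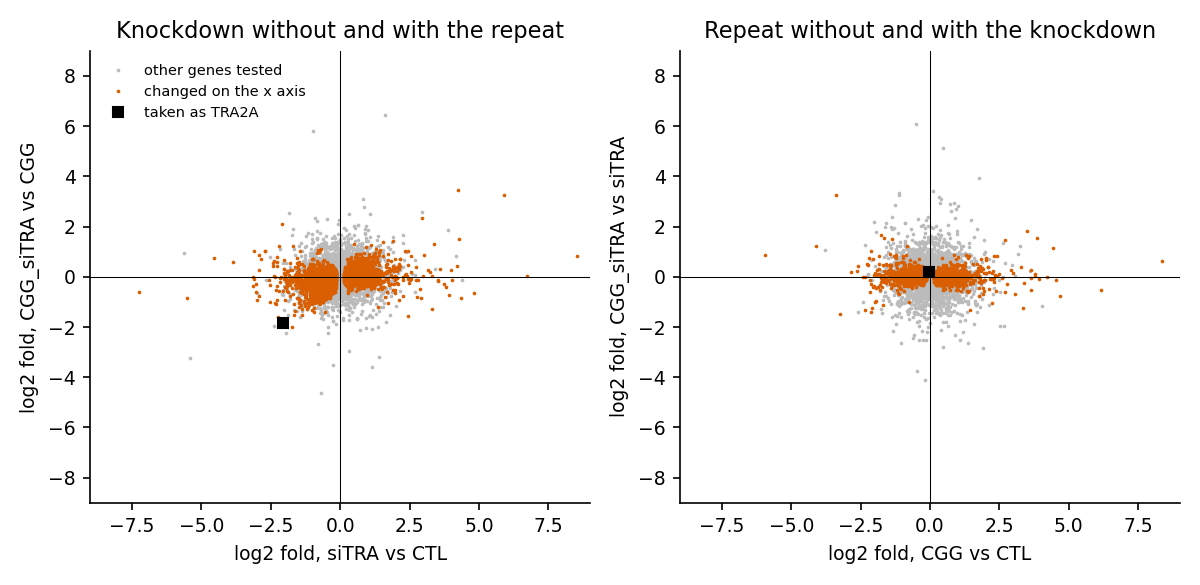
Log2 fold changes of all tested genes, with the knockdown without and with the repeat on the left and the repeat without and with the knockdown on the right. Genes changed in the comparison on the x axis are orange and the gene taken as TRA2A is a black square. The left cloud leans upward (r = 0.176) and the right one does not (r = -0.041).

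The interaction test called many genes, led by genes whose counts set CTL apart from the other groups, so it does not show which treatment they depend on. Regroupings of the libraries did not decide whether it rests on the grouping, since 5 of 100, the real one among them, called as many. The chromosome 7 gene at 134527592 to 134541408 rose with the knockdown in untreated cells but lay at 12690 ± 274 in CGG and 8967 ± 575 in CGG_siTRA (SD, n = 3). Its log2 interaction was -4.22 (SE 0.21, adjusted p = 3.63e-10, edgeR with Benjamini-Hochberg adjustment). A gene close by, at 134564788 to 134579875, moved alike, from 31.4 ± 25.3 in CTL to 421 ± 37.2 in CGG, 343.8 ± 54.4 in siTRA and 350.9 ± 75.6 in CGG_siTRA (SD, n = 3). How the authors' counting treated reads that fit similar genes is not stated. At chromosome 1, 11857464 to 11858931, and at chromosome 17, 6684713 to 6713567, the interaction had the other sign, 3.04 (SE 0.27) and 3.21 (SE 0.70). The second of these had an adjusted p of 0.476 when its highest bin stood for the gene (edgeR with Benjamini-Hochberg adjustment). The interaction passed an adjusted p under 0.05 for 2884 genes, 1522 above 0 and 1362 below 0, and for 1909 when the highest bin stood for each gene.

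Cells with TRA2A raised and lowered were also compared directly. At chromosome 20, 37289638 to 37317260, a gene lay at 2388 ± 58.8 in TRA_OE and 594 ± 83.6 in siTRA (SD, n = 3), against 1975 ± 64.1 in CTL, and at 707.8 ± 126 in CGG_siTRA (SD, n = 3). Its log2 difference between TRA_OE and siTRA was 1.94 (SE 0.10, adjusted p = 8.66e-10, edgeR with Benjamini-Hochberg adjustment). Its change in TRA_OE vs CTL was not called (log2 change 0.26, SE 0.10, adjusted p = 0.0561, edgeR with Benjamini-Hochberg adjustment). At chromosome 4, 73740506 to 73743716, a gene was lower in TRA_OE, at 134 ± 7.20 against 742.8 ± 162 in siTRA, with 97.95 ± 9.25 in CTL (SD, n = 3). It was also high in CGG, at 507.9 ± 57.2, and in CGG_siTRA, at 481.6 ± 61.9 (SD, n = 3). At chromosome X, 111881897 to 111903990, counts were 7.58 ± 6.03 in TRA_OE and 51.9 ± 6.39 in siTRA, with 30.53 ± 3.2 in CTL and 34.28 ± 21.6 in CGG_siTRA (SD, n = 3). By edgeR with Benjamini-Hochberg adjustment, TRA_OE vs CTL was called there (adjusted p = 0.0175). Neither siTRA vs CTL (adjusted p = 0.223, edgeR) nor CGG_siTRA vs CGG (adjusted p = 0.805, edgeR) was. The edgeR test with Benjamini-Hochberg adjustment called 4710 genes, 2520 higher in TRA_OE and 2190 lower, and 309 of the lower ones were at least 2-fold apart against 82 of the higher ones. The authors' scaling factors gave 3656 higher and 1548 lower, and the fit of these groups alone called 2945.

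Relative use of exon bins differed from CTL in each of CGG, TRA_OE and siTRA. The bin at chromosome 4, 56399401 to 56400783, rose from 81.8 ± 9.53 in CTL to 263.6 ± 16.8 in CGG and 236.2 ± 30.9 in siTRA (SD, n = 3), while the sum over its gene went from 18530 to 16290 and 12530. Neighbouring bins at chromosome 2, 232567215 to 232567527 and 232567528 to 232568020, rose from 79.8 ± 9.18 and 73.7 ± 10.8 in CTL to 306.6 ± 11.1 and 333 ± 37.6 in CGG (SD, n = 3). In siTRA they reached 305 ± 41.1 and 370.2 ± 29.5 (SD, n = 3). The log2 change in use of the second bin was 1.95 in CGG (adjusted p = 1.14e-26) and 2.04 in siTRA (adjusted p = 5.6e-29) by edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment. The bin at chromosome 10, 125841331 to 125842805, rose from 303.6 ± 38.6 to 800.5 ± 25.1 in CGG (SD, n = 3). In TRA_OE vs CTL the 5 bins with the smallest p, among those at least 2-fold changed with a mean of 50 or more, all lay in the TRA2A locus between 23504784 and 23522432. Their own counts stayed between 0.74 and 1.05 times CTL while the bins from 23505468 to 23521840 with a CTL mean of 10 or more rose. These 5 calls therefore do not show a change in the splicing of the cell's own TRA2A transcripts.

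Of 265486 bins in 12608 genes, edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment called 665 in CGG vs CTL (392 higher, 273 lower). It called 978 in TRA_OE vs CTL (491 higher, 487 lower) and 1348 in siTRA vs CTL (855 higher, 493 lower). These counts depended on single libraries. For CGG vs CTL they were 320, 332 and 267 without CTL library a, b or c, 285 and 268 without CGG library b or c, and 1011 when siTRA library b was left out of the shared spread. For TRA_OE vs CTL they were 403, 598 and 380 without CTL library a, b or c, and 501, 256 and 1493 without TRA_OE library a, b or c, the last with 1139 higher and 354 lower. For siTRA vs CTL they were 734, 606 and 675 without CTL library a, b or c.

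In the knockdown with the repeat present, a long bin at chromosome 13, 25331559 to 25336212, rose from 724.6 ± 82.9 in CGG to 1744 ± 302 in CGG_siTRA (SD, n = 3). It also rose from 774.3 ± 48.7 in CTL to 1955 ± 294 in siTRA (SD, n = 3). Its log2 change in use was 1.03 (adjusted p = 1.73e-15) and 1.22 (adjusted p = 6.69e-23) by edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment. The bin at chromosome 3, 33090425 to 33093788, in a group of overlapping genes, fell from 321.9 ± 25.9 to 124 ± 14.8 (SD, n = 3). At the TRA2A locus the bin from 23521841 to 23522120 stayed at 113 ± 31.1 in CGG_siTRA against 93.7 ± 14.6 in CGG (SD, n = 3) as the locus fell, so its use rose. The test called 358 bins, 269 higher and 89 lower. Without CGG library a, b or c it called 121, 106 and 163, without CGG_siTRA library b or c 66 and 578, and without siTRA library b 592. Outside the TRA2A locus, 91 bins were called in both knockdown comparisons, which share no library, and 86 of these moved the same way. Outside that locus 64 bins were called in both CGG_siTRA vs CGG and TRA_OE vs CTL, and 56 of these moved in opposite directions. Of the 963 called in TRA_OE vs CTL, however, 49.1% had the same sign in CGG_siTRA vs CGG, and of the 353 called in CGG_siTRA vs CGG, 38.5% had the same sign in TRA_OE vs CTL.

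The direct comparisons gave bin counts that rest on few libraries. The bin at chromosome 6, 70413578 to 70413645, lay at 112 ± 14.2 in CGG_siTRA and 56.2 ± 29.7 in siTRA (SD, n = 3; adjusted p = 0.0109, edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment). The bin at chromosome 19, 52269593 to 52269631, lay at 12.97 ± 4.37 and 92.5 ± 72.3 (SD, n = 3; adjusted p = 1.4e-05, edgeR's diffSpliceDGE with Benjamini-Hochberg adjustment). For CGG_siTRA vs siTRA 137 bins were called, 112 higher and 25 lower, but 1 without siTRA library b, 401 and 700 without siTRA library a or c, and 890, 7 and 19 without CGG_siTRA library a, b or c. For TRA_OE vs siTRA 1052 were called, 273 higher and 779 lower, against 550 and 666 without TRA_OE library c. That count was 463 and 358 without TRA_OE library a or b, and 359 and 2511 without siTRA library b or c.

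The authors' own DEXSeq tables listed more bins than diffSpliceDGE called, and some of the bins above were among them. Their adjusted p for the bin at chromosome 4, 56399401 to 56400783, was 7.09e-65 in CGG vs CTL. A bin at chromosome 1, 85577984 to 85578150, in a group of overlapping genes, fell from 450.7 ± 20.1 in CTL to 136.6 ± 10.1 in CGG, 186.3 ± 38.2 in siTRA and 139 ± 16.3 in CGG_siTRA (SD, n = 3). The bin at chromosome 16, 83914956 to 83916171, also in such a group, fell from 255.7 ± 12.1 in CTL to 150 ± 6.48 in CGG_siTRA and 132 ± 15.1 in siTRA (SD, n = 3). At an adjusted p under 0.05 their tables held 5914 bins for CGG vs CTL, 4209 for TRA_OE vs CTL and 5237 for siTRA vs CTL. They held 8862 for CGG_siTRA vs CGG, 10593 for CGG_siTRA vs CTL and 1872 for TRA_OE vs siTRA. The bins called by diffSpliceDGE were also in their lists for 93.7% in CGG vs CTL, 67.9% in TRA_OE vs CTL, 76.0% in siTRA vs CTL, 77.1% in CGG_siTRA vs CGG and 54.1% in TRA_OE vs siTRA, each in the same direction. Conversely, the 623 bins of CGG vs CTL and the 276 of CGG_siTRA vs CGG in both lists were a small part of the authors' 5914 and 8862.

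The authors' EventPointer tables held 6311 events each, counted here at other thresholds than the bins. The cassette exon event at chromosome 10, 26770345 to 26777065, had a change in percent spliced in of -0.25 as a fraction, both in CGG vs CTL (the authors' EventPointer p = 1.1e-15) and in TRA_OE vs CTL (the authors' EventPointer p = 5.9e-14). Counts of the bin inside it, 26771075 to 26771089, as a share of the counts of its gene, were 2.47 ± 0.0952% in CTL, 1.46 ± 0.211% in CGG, 1.31 ± 0.174% in TRA_OE, 1.61 ± 0.0406% in siTRA and 1.7 ± 0.171% in CGG_siTRA (SD, n = 3). The cassette exon event at chromosome 15, 59664120 to 59668892, changed by -0.20 in CGG vs CTL, and its bin at 59668103 to 59668138 fell from 1.84 ± 0.126% to 1.21 ± 0.0823% of its gene's counts (SD, n = 3). At an EventPointer p under 0.001 and a change of at least 0.1, 37 events passed in CGG vs CTL, 10 higher and 27 lower, of which 15 were cassette exons and 12 of these were lower; cassette exons made up 1580 of the events listed. In TRA_OE vs CTL 31 passed, 10 higher and 21 lower, and 9 of 11 cassette exons were lower. In both comparisons 12 events passed, but these share the CTL libraries, and the tables hold no values per library from which a value for unchanged groups could be simulated.

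**Figure D5:**
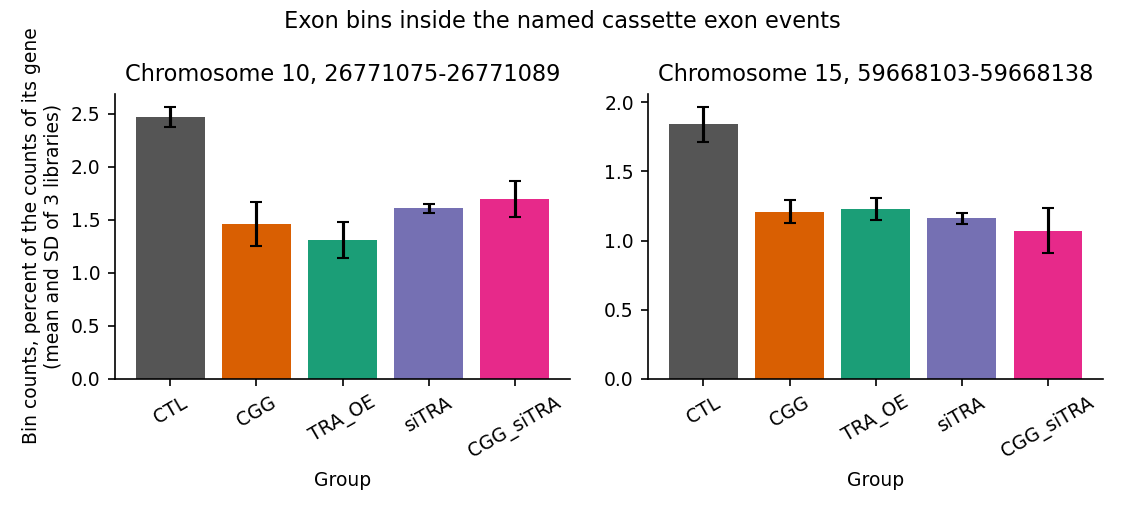
Counts of an exon bin as a percent of the counts of its gene in each group, as bars for the mean with the SD of 3 libraries, for the bins inside the named cassette exon events on chromosomes 10 and 15. Both bins are highest in CTL, at 2.47% and 1.84%, and lower in each treated group with counts.

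For the repeat combined with raised TRA2A, only these event tables were available. A retained intron at chromosome 22, 28796121 to 28796148, changed by -0.23 in CGG_TRA vs CGG (the authors' EventPointer p = 7.43e-05). A complex event at chromosome 17, 42613048 to 42665476, changed by -0.20 (the authors' EventPointer p = 0.000958). In CGG_TRA vs CGG_siTRA, an alternative last exon at chromosome 1, 35178036 to 35187001, changed by -0.20 (the authors' EventPointer p = 0.000299). For CGG_siTRA vs siTRA, a complex event at chromosome 11, 13421838 to 13463092, changed by 0.21 (the authors' EventPointer p = 9.78e-05). The thresholds were passed by 7 events in CGG_TRA vs CGG, 17 in CGG_TRA vs CGG_siTRA and 10 in CGG_siTRA vs siTRA. Of the 37 events of CGG vs CTL, 13 had the same sign in CGG_siTRA vs siTRA and 0 passed there, and that table held 398 events with an EventPointer p under 0.05. The direction of these changes is the first-named group minus the second, read from the bins of cassette exons, which could not be done for tables with CGG_TRA.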

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

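The slope of the repeat's effect and the handling of the CTL libraries were weighed only after the result was seen.

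With the repeat added to knocked-down cells by transfection, 2 genes were called, while 3613 differed between CGG and CTL. Siting the cause in siTRA library b, which could widen the spread and hide the effect, is not borne out, because 2 genes were called without it as well, but the count did depend on other choices: 682 without CGG_siTRA library a and 540 with DESeq2. A response shared by all treated groups and absent from CTL is a candidate explanation. The slope of the fold change with the knockdown on that without it was -0.022 (jackknife SE 0.043) over the 3613 genes. An unchanged effect of the repeat would give a positive slope. It would lie below 1, because the genes were picked by the same noisy fold changes, and its value was not simulated. CTL libraries that were handled apart from the others could give the same slope of -0.022, and no batch or date label tells these apart.

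Library b of siTRA correlated least with the others. Its depth, the lowest at 121142115 bin counts, might explain this, but with libraries a and c thinned to that total the gap in correlation was 0.0078, against 0.0088 before. Uneven coverage along genes is a candidate: the median share of a gene's counts beyond the midpoint toward the 3' end was 39.8% in this library, against 36.7% to 38.0% in the other 14. Whether a shift of this size lowers the correlation was not tested.

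The interaction was called for 2884 genes, and 5 of 100 groupings of the libraries, the real one among them, called as many. The other 4 all kept CTL and siTRA apart, as 7 of the 99 drawn did, and the highest of them called 4705 genes. Groupings that mixed CTL with siTRA called at most 84. Keeping CTL and siTRA apart leaves the knockdown's own effect in the contrast, and mixing them widens the spread, so these counts do not decide whether the interaction rests on the grouping.

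Single genes were picked out because the knockdown's effect differed, by the interaction test, between cells with and without the repeat. The interactions of -4.22 and -3.69 at chromosome 7, 134527592 and 134564788, came from counts that were low only in CTL. That of 3.04 at chromosome 1, 11857464, came from counts that were high only in CTL. The interaction of 3.21 at chromosome 17, 6684713, was 1.0 (adjusted p = 0.476, edgeR with Benjamini-Hochberg adjustment) with the highest bin per gene.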

How the results depend on the processing

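The settings with the authors' scaling factors, the highest bin per gene and all genes with recovered reads were chosen only after the result was seen, and so was leaving out siTRA library b where it was not a compared group.

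No paired analysis was possible because the columns carry no replicate numbers. The gene lists and all gene and bin tests of CGG_TRA were not run, for want of names and of counts.

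Of 135 alternative gene counts 119 stayed within a factor of 1.5, of 63 alternative bin counts 19 did, and 0 named genes reversed.

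With only the groups compared, 6295 genes were called for CGG vs CTL, 2945 for TRA_OE vs siTRA and 1 for CGG_siTRA vs siTRA. limma with pseudocounts of 1, 0.5 and 5 called 2374, 2373 and 2382 genes for CGG_siTRA vs CGG, and the authors' scaling factors 2330. Each of these called 5 for CGG_siTRA vs siTRA, where DESeq2 called 540. With the highest bin per gene the interaction was called for 1909 genes.

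Leaving out 1 library gave 2569 to 4683 genes for CGG vs CTL, 3008 to 5366 for TRA_OE vs CTL, 4627 to 5662 for siTRA vs CTL, and 941 to 2245 for CGG_siTRA vs CGG. For CGG_siTRA vs siTRA the range was 2 to 682, for TRA_OE vs siTRA 3377 to 4567, and for the interaction 2061 to 3368.

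limma's diffSplice with pseudocounts of 1 and 5 called 3516 and 2794 bins for CGG vs CTL, 3424 and 2906 for TRA_OE vs CTL, 6320 and 5194 for siTRA vs CTL, 2971 and 2504 for CGG_siTRA vs CGG, 4585 and 2985 for CGG_siTRA vs siTRA, and 6309 and 5153 for TRA_OE vs siTRA. Its surplus may be false calls, since 1813 of its 1973 calls in simulated data lay in genes without a changed bin, and 3516 is its count for the comparison simulated. Those data were drawn from the count model that diffSpliceDGE assumes. With bins above 0 in 3 libraries, 81 were called for CGG_siTRA vs siTRA.

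Leaving out 1 library gave 267 to 1011 bins for CGG vs CTL, 256 to 1493 for TRA_OE vs CTL, 606 to 1823 for siTRA vs CTL, 66 to 592 for CGG_siTRA vs CGG, 1 to 890 for CGG_siTRA vs siTRA and 358 to 2511 for TRA_OE vs siTRA. The cause was not tested. Directions also depended on these settings: CGG vs CTL went from 392 higher and 273 lower to 1418 and 2098 with diffSplice at a pseudocount of 1, siTRA vs CTL from 855 and 493 to 2732 and 3588, TRA_OE vs CTL from 491 and 487 to 1329 and 2095, and TRA_OE vs siTRA from 273 and 779 to 3072 and 3237. Without TRA_OE library c, TRA_OE vs CTL had 1139 higher and 354 lower, and CGG_siTRA vs siTRA went from 112 and 25 to 1 and 6 without CGG_siTRA library b.

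At an adjusted p under 0.01 the authors' DEXSeq tables held 3337 bins for CGG vs CTL, 4313 for CGG_siTRA vs CGG, 5884 for CGG_siTRA vs CTL, 2394 for TRA_OE vs CTL, 2707 for siTRA vs CTL and 918 for TRA_OE vs siTRA. At 0.1 siTRA vs CTL held 7876. Events with a change of 0.2 or more numbered 3 for CGG vs CTL, 2 for CGG_TRA vs CGG, 1 for CGG_TRA vs CGG_siTRA, 3 for CGG_siTRA vs siTRA and 4 for TRA_OE vs CTL. At an EventPointer p under 0.01 they numbered 16, 31 and 21 for CGG_TRA vs CGG, CGG_TRA vs CGG_siTRA and CGG_siTRA vs siTRA, and 50 for TRA_OE vs CTL. By Benjamini-Hochberg adjustment they numbered 4 for CGG_TRA vs CGG and 2 for CGG_siTRA vs siTRA.

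The correlation of the knockdown effects was 0.147 to 0.172 with 1 library left out and 0.327 over genes with a mean of 100 or more. For the repeat's effects it was -0.080 to -0.017, and for raised against lowered TRA2A -0.076 to -0.045, or -0.131 over genes with a mean of 100 or more.

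Of 519 refits of named genes 513 kept their call. At chromosome 17, 28703197, the gene had an adjusted p of 0.113 and 0.149 without CGG library a and c, and of 0.0776 and 0.0711 without CGG_siTRA library a and b (edgeR with Benjamini-Hochberg adjustment). At chromosome 12, 57516588, the gene had 0.0629 with only the groups compared, and the gene at chromosome 17, 6684713, had 0.476 for the interaction with the highest bin per gene.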

Other observations

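Groupings of the libraries other than the real one were tested as planned; the shift of the bin test to diffSpliceDGE, which sets the bins used below, the values without a link and the counts for lists changed in both knockdowns were chosen only after the result was seen.

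At several genes named for a large change against CTL, the treated groups with counts resembled each other more than CTL. Picking genes by that change favours this pattern, so they do not show how common it is. At chromosome 3, 111592900 to 111595443, a gene lay at 73.7 ± 8.11 in CTL and at 16.5 ± 4.02 in CGG, 17.5 ± 6.81 in TRA_OE and 15.35 ± 7.83 in CGG_siTRA (SD, n = 3). At chromosome 2, 96497646 to 96505357, a gene lay at 3.16 ± 2.86 in CTL, 41.75 ± 5.19 in CGG and 46.95 ± 5.53 in CGG_siTRA (SD, n = 3). Levels at chromosome 6, 93240020 to 93419547, were lowest in both groups with the repeat, at 5.86 ± 3.00 in CGG and 7.15 ± 1.11 in CGG_siTRA, against 21.4 ± 9.22 in siTRA (SD, n = 3), but CGG_siTRA vs siTRA was not called there (adjusted p = 0.157, edgeR with Benjamini-Hochberg adjustment). Genes named for other comparisons did not all set CTL apart. At chromosome 15, 41230839 to 41281890, counts were 28280 ± 545 in CTL, 29490 ± 1090 in TRA_OE and 8110 ± 1030 in siTRA (SD, n = 3). At chromosome 10, 62811996 to 62816366, counts were 89.99 ± 14.6 in CTL, 83 ± 18 in siTRA and 30.92 ± 14.3 in CGG (SD, n = 3).

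Genes changed in both knockdown comparisons moved the other way in TRA_OE vs CTL about as often as independent lists would, and the difference was not tested. TRA2A apart, 589 genes were lower in both knockdowns, of which 90 were higher in TRA_OE (independent lists 85.5) and 116 lower (84.4). Of 315 genes higher in both knockdowns, 44 were lower in TRA_OE (45.1) and 66 higher (45.7). In these counts siTRA and TRA_OE share the CTL libraries, which favours changes in the same direction, so they do not decide on a tie to the TRA2A level.

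One hypothesis was that genes and bins changed by the knockdown with the repeat present follow the TRA2A level, and would move the other way in TRA_OE vs CTL, which shares no library. Of 1506 such genes other than TRA2A, 60.6% moved the other way, against 54.6% of all tested genes and 50.5% without a link at the same shares of rises and falls, with a range of 58.0% to 63.5% when 1 library was left out. Over 60% was the value set in advance, so the range spans it. Of the lead bins of 178 genes, 61.8% moved the other way, where the same shares of rises and falls give 61.4% without a link. Lead bins that rose moved the other way in 67.1% of 149 and those that fell in 34.5% of 29, so most of both were lower in TRA_OE. This test therefore does not decide on a tie to the TRA2A level, and the 56 of 64 bins called in both comparisons that moved in opposite directions were not tested against such a value.

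Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. Every split but the real one mixes the compared groups. A difference between the groups then widens the spread, so low counts in those splits are favoured and do not measure chance. For genes, the real split was the only 1 to reach its count in CGG vs CTL (3613), TRA_OE vs CTL (4318), siTRA vs CTL (5667), CGG_siTRA vs CGG (1507) and TRA_OE vs siTRA (4710), with 0 genes in the highest other split of each. For CGG_siTRA vs siTRA, 4 of 10 splits called 2 or more, the highest other 3. For bins, the real split was the only 1 to reach its count in CGG vs CTL (665, highest other 1), TRA_OE vs CTL (978, highest other 260), siTRA vs CTL (1348, highest other 29) and CGG_siTRA vs CGG (358, highest other 92). In CGG_siTRA vs siTRA 5 of 10 splits, the real one among them, called 137 bins or more. Of these, 1 called 620, several times the real count, so a count of this size does not need the real grouping. What drives that split was not tested, and the real count itself was 1 without siTRA library b and 7 without CGG_siTRA library b. In TRA_OE vs siTRA 2 of 10 called 1052 or more, the highest other 1316.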
